A study of Mus musculus with 187 samples.

How the data were processed

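Single immune cells from MC38 tumours of 45 hTREM2 mice were sorted into 187 plates of 384 wells, 115 plates from a CD45 gate and 72 from a gate for CD90.2 and/or NK1.1 (the enriched gate), with doublets and dead cells excluded at sorting, per the labels' protocols. No doublet caller was run here. Libraries were made with SPID-seq, an adapted form of MARS-seq that barcodes polyadenylated RNA by well, per the labels' protocols. Reads were demultiplexed with bcl2fastq 2.15.0.4 and placed on mm10, per the submitters' processing notes. The aligner and the counting tool are not given in the sources used here.

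The deposited tables hold molecule counts (UMIs) of 52634 genes per well, one table per plate, with no normalisation, and 42379 genes had at least 1 UMI. The authors' cell table, as deposited, names the plate and well of 45505 cells of the 71808 wells, the number the labels state, and gives each cell's cluster, total and number of genes. It also gives the percentage of mitochondrial counts per cell, which the authors computed and which reaches 9.99841. The authors' totals have a median of 2339 UMIs against 2982 for the same wells here. The authors thus left out some genes, by a rule not given in the sources used here. All genes were kept. Mitochondrial genes took 3.75% and 5 genes resembling ribosomal RNA 11.4% of UMIs. The 92 spike-in sequences had 0 UMIs and were left out.

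The authors' 20 clusters were taken as given and joined into 7 classes, namely NK cells, CD8 T cells, monocytes and macrophages, dendritic cells, regulatory T cells, other T cells (annotated as neither CD8 nor regulatory) and granulocytes. The mouse was the replicate, named by its group and the replicate number in its label, and mice had 208 to 1506 cells. In the text, "+" joins agents given together. The 9 groups fall in 3 batches with no group in common, so 8 comparisons were made, each within a batch. Numbers 21 to 30 occur in more than one batch for different mice, and no comparison shares a number between its groups.

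For each class, UMIs were summed per mouse over both gates, with at least 10 cells per mouse and 3 mice per group. Genes were filtered with filterByExpr, scaled with TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, with all groups of the batch in the fit. P-values were adjusted by Benjamini-Hochberg within class and comparison, and an adjusted p under 0.05 is called. Values in CPM beside a test use the TMM-scaled totals of that fit, levels over all 9 groups those of 1 scaling over the 45 mice, and plotted levels plain totals. Log2 fold changes are given ± their standard error. Shares of cells were tested with edgeR on counts of cells (at least 20 cells of the gate per mouse) and by a two-sided exact permutation test, whose smallest p is 0.00794 for 5 against 5 mice and for 4 against 5. Interactions used all 9 groups in one fit (45 mice, 43 for CD8 T cells). CPM and percent values of shares were computed here from the deposited counts.

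Before the data were examined, 23 gene lists were fixed. They are cytotoxic effector, IL-2 and STAT5 response, proliferation, T cell exhaustion and activation, naive and memory, NK maturation, interferon-gamma response, antigen presentation by MHC class I and by class II, type I interferon response, TREM2-associated macrophage, monocyte, hypoxia and glycolysis, inflammatory cytokines and chemokines, regulatory T cell, dissociation stress, and markers of other cells (neutrophil, macrophage, T and NK, B cell, fibroblast, red blood cell, tumour and epithelial). A list was tested with at least 3 measured members. Fibroblast, red blood cell and tumour lists never had 3, and the B cell list had 3 in a single comparison. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of a class and comparison. Numbers of members that rose and fell use the adjustment over all genes, and "list alone" gives the numbers when adjusted over the members of the list alone, where these differ.

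Genes named in the text follow a rule fixed at the same time. Among called genes with a mean above 50 CPM they are the 4 with the highest and the 4 with the lowest fold change, ribosomal, mitochondrial, receptor-rearranged and predicted genes aside. In each list they are up to 4 members of smallest adjusted p, and always Trem2, Pdcd1, Ctla4, Il2ra, Il2rb and Il2rg.

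Alternatives were RLE scaling, no expression filter, DESeq2 1.42.0, at least 30 cells per mouse, only the groups compared in the fit, each mouse left out in turn, TMM or the exact test for shares, shares without granulocytes, T and NK shares over both gates, and 4 groups for interactions. Chosen after seeing the data were fits without the 2 mice of under 300 cells (MiTE144+aPD1 19 with 208 and MiTE144+aCTLA4 22 with 265), without the 5 genes resembling ribosomal RNA, without the proliferating NK or CD8 cluster and over all T cells other than regulatory ones, share interactions, RLE and single-mouse fits of interactions, all alternatives for macrophage states and named genes, and single-mouse values of called classes. Up to 100 other splits of the mice were fitted per result. The tests were also run on simulated data built on MiTE144 against aRSV. Of genes changed by a log2 of 1 or 2, it recovered 61% and 97% of 100 each in NK cells (8884 genes, 4.82% of calls false), 18.8% of 85 and 85.7% of 91 in CD8 T cells (4522 genes, 4.08% false), and 83% and 100% of 100 each in monocytes and macrophages (11016 genes, 6.63% false). The share test recovered a tripled CD8 share in 100% of 50 runs, and 12% of runs had a false call. Python 3.11.15 read the tables.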

Results

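Tumour-infiltrating immune cells of 45 hTREM2 mice with subcutaneous MC38 tumours were profiled one by one, 5 mice in each of 9 treatment groups. Per the labels, each antibody or fusion protein was given intravenously at 200 µg per dose on days 8 and 10, and the tumours were taken on day 11. The reference group received an antibody to respiratory syncytial virus (aRSV). The other groups received MiTE144, which the series title presents as an immunocytokine aimed at tumour-associated macrophages, an antibody to TREM2 (aTREM2), or checkpoint antibodies (aPD1, aCTLA4) alone or in combination. Treatment was bound to batch. The batch RunA held aRSV (4701 cells, 3169438 to 4097157 UMIs per mouse), aTREM2 (4949 cells, 3268612 to 5265514), MiTE144 (4851 cells, 2670233 to 4080363) and MiTE144+aPD1 (3614 cells, 792035 to 4374541). RunE held aPD1 (6310 cells, 3061953 to 5223180) and aTREM2+aPD1 (4914 cells, 2073824 to 3829783). Plate1 held aCTLA4 (6433 cells, 4271525 to 5893991), aTREM2+aCTLA4 (5272 cells, 1398002 to 5435095) and MiTE144+aCTLA4 (4461 cells, 646447 to 6230377). Groups were tested only within a batch, in 8 comparisons, with the mouse as the replicate.

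The authors' annotation places 45505 cells in 20 clusters, and the classes used here carried the genes of their lineage. Ncr1, an activating receptor of natural killer (NK) cells, averaged 657 CPM in the 9899 NK cells against 5.99 CPM in monocytes and macrophages. Cd8a, a T cell coreceptor, averaged 993 CPM in the 2368 CD8 T cells and 1.54 CPM in NK cells. Csf1r, a growth factor receptor of macrophages, stood at 701 CPM in the 23313 monocytes and macrophages and 12.6 CPM in NK cells. The granulocyte gene S100a8, coding for an alarmin, averaged 16800 CPM in granulocytes and 65.0 CPM in monocytes and macrophages. Foxp3, which defines regulatory T cells, stood at 545 CPM in those cells. A cell held a median of 2982 UMIs, 2184 in NK cells, 3858.5 in CD8 T cells and 3744 in monocytes and macrophages. Of cells of the enriched gate, 32.6% were annotated as myeloid, so shares in that gate are given among its T and NK cells.

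MiTE144 alone changed which immune cells were found in the tumour. The CD8 clusters and granulocytes took more of the CD45 gate than under aRSV and dendritic cells less. In T and NK cells the proliferating clusters of both lineages grew. Per mouse (n = 5 each, mean ± SD), CD8 T cells were 5.46% ± 3.57 against 1.90% ± 1.37, log2 +1.54 ± 0.54, adjusted p = 0.0222, exact permutation p = 0.0476. Granulocytes were 7.74% ± 4.61 against 2.21% ± 1.12, log2 +1.81 ± 0.50, adjusted p = 0.00575, exact p = 0.0318. Dendritic cells were 3.02% ± 0.949 against 9.31% ± 4.29, log2 -1.61 ± 0.37, adjusted p = 0.00238, exact p = 0.00794, with all 5 MiTE144 mice below all 5 aRSV mice. The NK share was 19.1% ± 8.03 against 11.7% ± 3.13, log2 +0.70 ± 0.32, adjusted p = 0.0715, exact p = 0.119, not called. The adjusted exact test called 0 of 7 classes (edgeR 3). Its lowest adjusted p, 0.0556, is the least that 1 class alone can reach. Leaving out MiTE144 mouse 12 brought the edgeR count to 5, and the CD8 T cell call was lost with others left out (+1.42 and +1.29 without aRSV 1 and 4, +1.09 without MiTE144 14).

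Among T and NK cells of the enriched gate, the proliferating NK cluster was 18.2% ± 3.79 against 1.77% ± 1.13, log2 +3.40 ± 0.40, adjusted p = 1.16e-08, exact p = 0.00794. The proliferating CD8 cluster was 7.09% ± 1.94 against 1.15% ± 1.89, log2 +2.71 ± 0.65, adjusted p = 0.00115, exact p = 0.00794. The clusters annotated as less mature NK cells shrank. Early NK cells were 6.93% ± 3.17 against 18.2% ± 9.16, log2 -1.36 ± 0.39, adjusted p = 0.00376. Intermediate NK cells were 7.53% ± 1.99 against 18.2% ± 5.69, log2 -1.26 ± 0.34, adjusted p = 0.00306. Effector T cells not annotated as CD8 were 8.22% ± 3.17 against 16.2% ± 5.16, log2 -0.93 ± 0.37, adjusted p = 0.0381, a call lost with 1 mouse left out (-0.92, -0.96 and -0.74 without aRSV 2, 3 and 5, -0.79, -0.92 and -0.84 without MiTE144 12, 13 and 15). The clusters were named by genes that themselves differ between groups, so shares and gene values are not independent. Of the 11 clusters 5 were called by edgeR, 3 by the exact permutation test and 2 with TMM scaling.

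**Figure D1:**
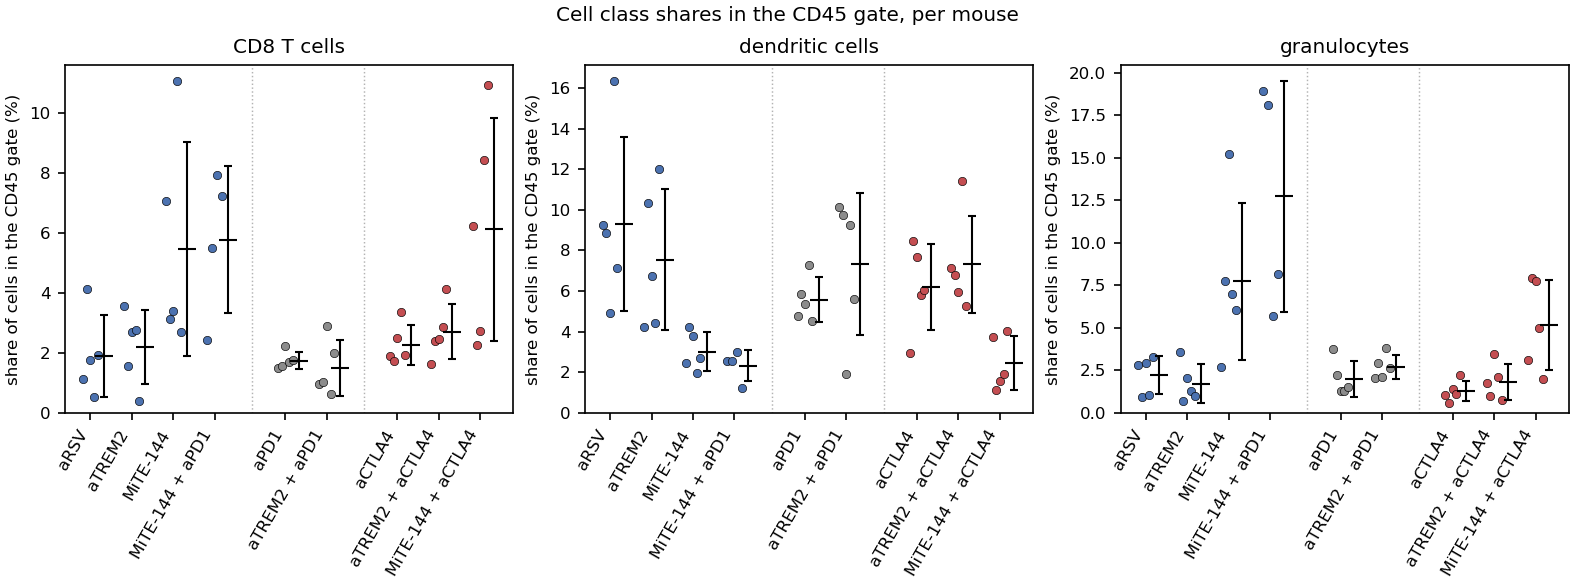
Share of CD8 T cells, dendritic cells and granulocytes among cells of the CD45 gate, in percent, for the 9 treatment groups. Each point is 1 mouse, bars give the mean and error bars the SD (n = 5, 4 for MiTE144+aPD1), and dotted lines separate the batches. Dendritic cells averaged 3.02% under MiTE144 and 9.31% under aRSV.

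**Figure D2:**
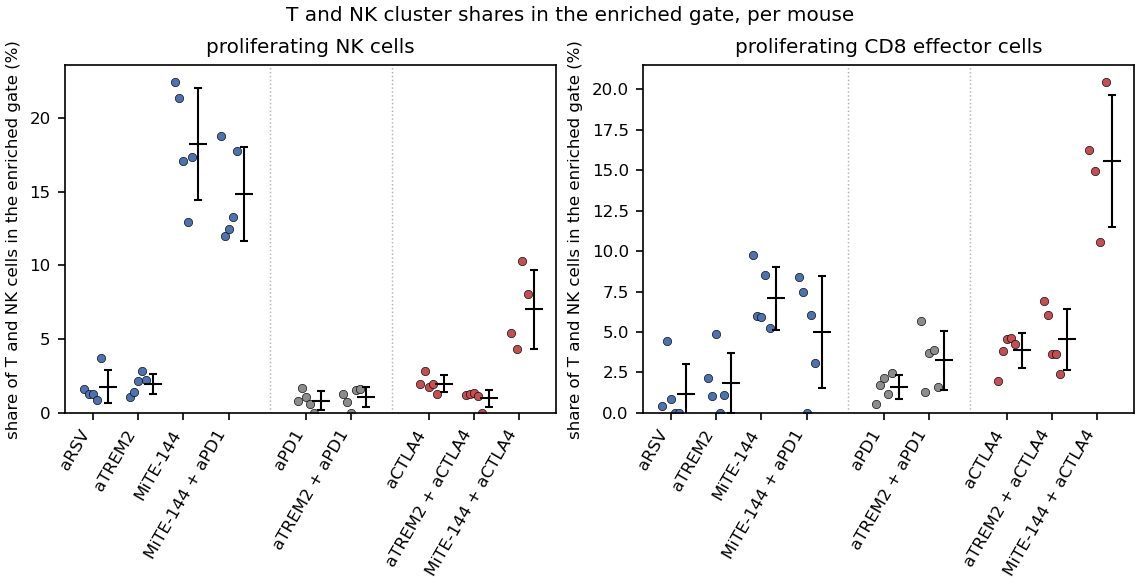
Share of the proliferating NK and CD8 clusters among T and NK cells of the enriched gate, in percent, for the 9 groups. Each point is 1 mouse, bars give the mean and error bars the SD (n = 5, 4 for MiTE144+aCTLA4), and dotted lines separate the batches. The proliferating NK cluster averaged 18.2% under MiTE144 and 1.77% under aRSV.

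Of the 3 main classes, NK cells had the most called genes under MiTE144. Cell-cycle genes were higher and target genes of interleukin-2 (IL-2) signalling and of interferon lower. Of 9126 genes tested, 700 rose and 679 fell against aRSV. Cell-cycle genes rose together, and of the proliferation list 26 of 26 rose and 0 fell (adjusted p = 8.52e-62, 1.05e-05 with an estimated correlation, below marked estimated). Mki67, coding for a chromosome coat protein of dividing cells, stood at 302 ± 101 against 25.0 ± 11.8 CPM (log2 fold change +3.50 ± 0.26, adjusted p = 4.57e-12). The linker histone Hist1h1b (+4.31 ± 0.63), the core histone Hist1h2ap (+3.23 ± 0.42), the ribonucleotide reductase subunit Rrm2 (+2.72 ± 0.27), the tubulin regulator Stmn1 (+2.38 ± 0.20) and the chromatin protein Hmgb2 (+1.92 ± 0.17) rose with it. Klrg1, an inhibitory receptor of mature NK cells, went to 334 ± 58.3 against 32.0 ± 22.0 CPM (adjusted p = 5.9e-11). The granule protease Gzmk (+2.92 ± 0.33), the pore protein Prf1 (+0.88 ± 0.16) and the inhibitory receptor Havcr2 (+3.14 ± 0.79), also known as TIM-3, were higher. In each of these genes all 5 MiTE144 mice lay above all 5 aRSV mice. The cytotoxic effector list as a whole was split, with its members moving both ways (4 rose and 4 fell of 18, list alone 4 and 5, adjusted p = 0.356). The protease Ctsw (-0.88) and the chemokine Xcl1 (-2.01), which draws in conventional dendritic cells, fell, Xcl1 to 822 ± 448 against 3315 ± 1000 CPM. Without the cells of the proliferating cluster 354 genes were called, 306 of them among the 1379.

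Among the genes that fell in NK cells were targets of cytokine signalling. In the IL-2 and STAT5 response list 0 of 20 rose and 13 fell (list alone 2 and 14, adjusted p = 3.98e-09, 0.00210 estimated). They included the feedback inhibitors Cish (-1.35 ± 0.23) and Socs1 (-1.24 ± 0.22), the survival factor Bcl2 (-1.01 ± 0.15), the kinase Pim2 (-1.55 ± 0.22), the cyclin Ccnd2 (-1.100 ± 0.14) and the high-affinity receptor chain Il2ra (-1.11 ± 0.30). The shared receptor chains Il2rb (-0.32 ± 0.14, adjusted p = 0.123) and Il2rg (-0.35 ± 0.14, adjusted p = 0.0932) were not called, nor were the checkpoint genes Pdcd1 (-0.29 ± 0.43, adjusted p = 0.715) and Ctla4 (-0.41 ± 0.36, adjusted p = 0.495). In the type I interferon response list 0 of 18 rose and 15 fell (list alone 0 and 18, adjusted p = 2.66e-17, 0.0374 estimated). The antiviral genes Oasl2 (-2.86 ± 0.36), Ifit3 (-2.47 ± 0.36), Isg20 (-1.21 ± 0.22) and Bst2 (-1.17 ± 0.19) fell, and so did the chemokine Cxcl10, which recruits T cells, from 369 to 24.1 CPM (-3.87 ± 0.44, adjusted p = 4.67e-08). The interferon-gamma list had the same direction (1 rose and 13 fell of 24, list alone 2 and 14, adjusted p = 9.17e-07, 0.0656 estimated), with falls of the transcription factor Irf1 (-1.04) and the checkpoint ligand Cd274 (-1.25). In the class I list 0 of 12 rose and 7 fell (adjusted p = 1.01e-04, 0.101 estimated), among them the transactivator Nlrc5 (-1.26) and the class I chains H2-Q6 (-0.99), H2-T23 (-0.75) and H2-K1 (-0.53). In the class II list 0 of 6 rose and 3 fell (list alone 0 and 4, adjusted p = 0.00880, 0.101 estimated), H2-Aa (-1.59) among them, perhaps as myeloid RNA. Calls that ended when 1 mouse was left out, with the log2 fold change then, were Il2ra (-0.88 without aRSV 2) and H2-Aa (-1.27 without aRSV 1).

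Maturation, exhaustion and metabolic genes of NK cells moved in both directions, and their lists were not called. The costimulatory receptor Cd27 (-1.80 ± 0.38), a marker of immature NK cells, the receptor Tigit (-0.88), the nuclear receptor Nr4a2 (-1.60), the chromatin organiser Satb1 (-1.39) and the angiogenic factor Vegfa (-2.66) fell. The mast cell protease Cma1 (+2.29), which was at -0.49 without the proliferating cluster, the transcription factor Lef1 (+1.09) and the glycolytic enzymes Eno1 (+1.07) and Pkm (+0.88) rose. By list the results were NK maturation (2 rose and 2 fell of 12, list alone 5 and 3), exhaustion and activation (2 rose and 3 fell of 16), naive and memory (1 rose and 2 fell of 11) and hypoxia and glycolysis (4 rose and 3 fell of 18, list alone 9 and 3), adjusted p = 0.0572 to 0.317. Stress genes induced by tissue digestion were lower, Junb (-1.42) among them, by list dissociation stress (0 rose and 5 fell of 16, list alone 0 and 8, adjusted p = 6.24e-04), adjusted p = 0.169 with an estimated correlation. In NK wells the TREM2-associated macrophage, monocyte, inflammatory cytokine, regulatory T cell, macrophage and T and NK lists were not called (adjusted p = 0.0912 to 0.552).

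**Figure D3:**
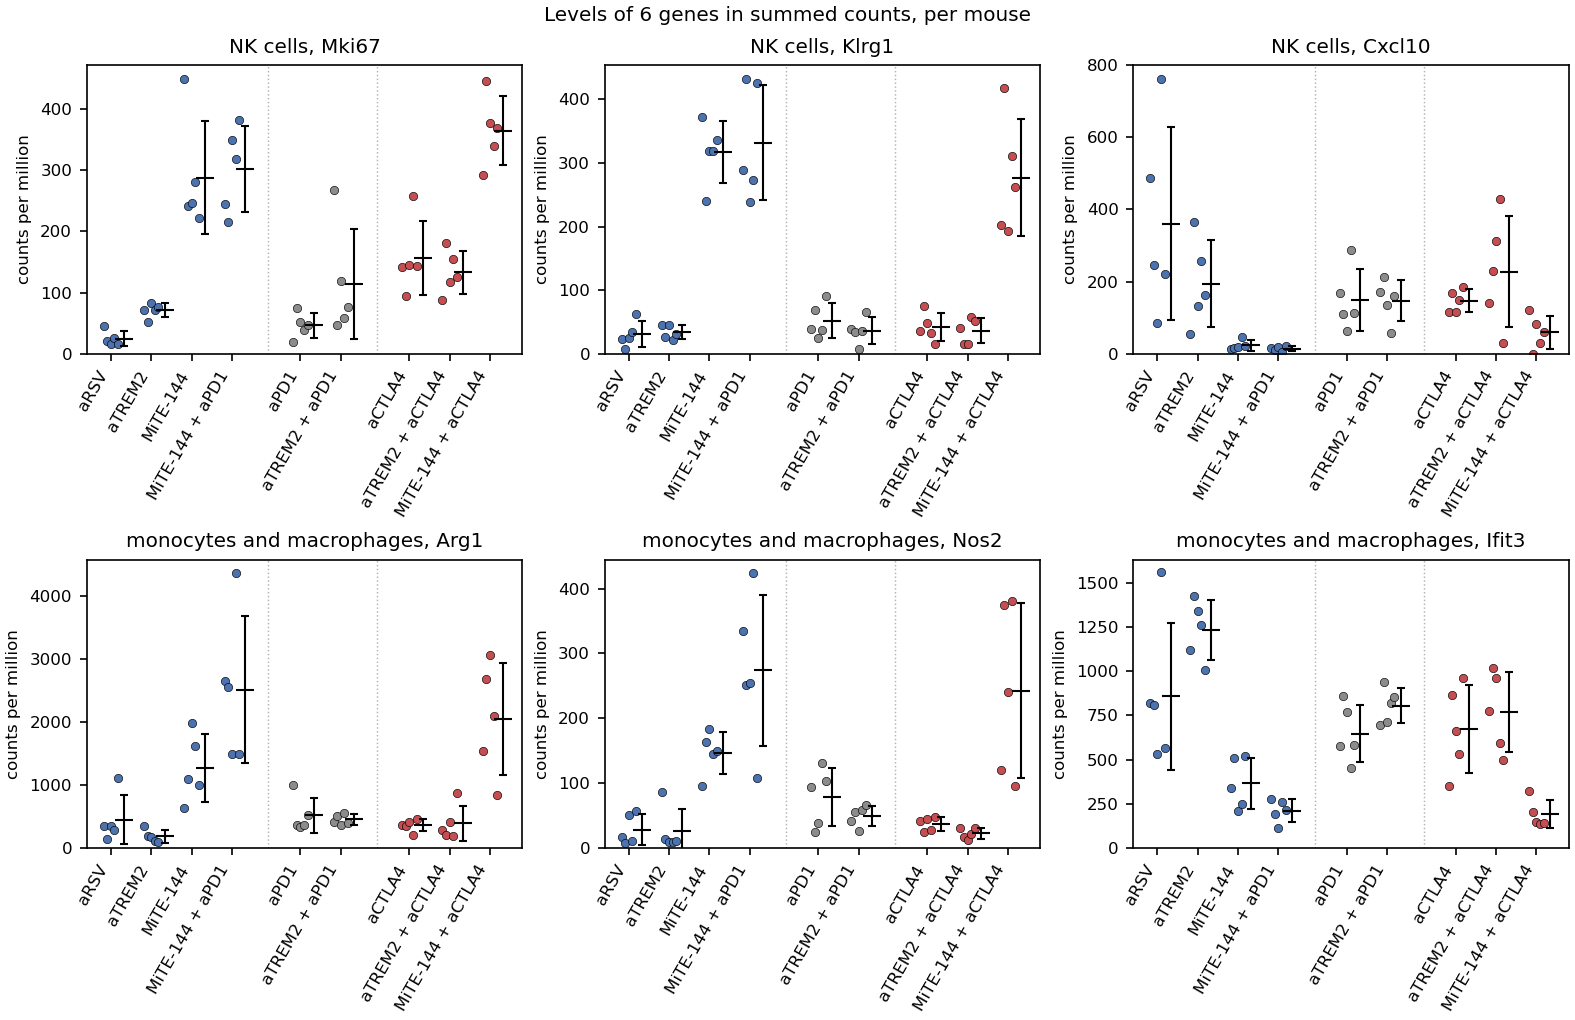
Level of Mki67, Klrg1 and Cxcl10 in NK cells and of Arg1, Nos2 and Ifit3 in monocytes and macrophages, in CPM of all UMIs, for the 9 groups. Each point is 1 mouse, bars give the mean and error bars the SD (n = 5), and dotted lines separate the batches. Klrg1 is at least 240 CPM in each MiTE144 mouse and at most 63.0 CPM in each aRSV mouse.

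The CD8 class joins 2 clusters mixed differently in the groups, with 112 exhausted and 104 proliferating cells under MiTE144 in the enriched gate and 58 and 10 under aRSV. Against aRSV (n = 5 and 4 mice, 378 and 121 cells), 3 of 5267 genes were called and all 3 fell. They were the orphan nuclear receptor Nr4a3 (-2.21 ± 0.37, adjusted p = 0.00392), at 68.8 ± 26.8 against 313 ± 107 CPM, the growth-arrest gene Gadd45b (-2.03 ± 0.35, adjusted p = 0.00392) and the phosphatase Dusp4 (-1.96 ± 0.38, adjusted p = 0.0186). In the proliferation list 0 of 26 rose and 0 fell (list alone 17 and 0, adjusted p = 1.39e-25, 0.0190 estimated). In the exhaustion and activation list 0 of 14 rose and 0 fell (list alone 0 and 6, adjusted p = 1.26e-08, 0.0190 estimated). The regulatory T cell list had a lower level (0 called of 8, list alone 0 and 3, adjusted p = 1.36e-04, 0.0288 estimated). The inflammatory cytokine list had a lower level (0 called of 3, list alone 0 and 2, adjusted p = 0.00868, 0.201 estimated). The checkpoint genes Pdcd1 (-0.64 ± 0.22, adjusted p = 0.287) and Ctla4 (-1.14 ± 0.34, adjusted p = 0.196) were not called. The count was 68 without the expression filter, 34 by DESeq2 and 185 over all T cells other than regulatory ones. Without the proliferating CD8 cluster (4 mice each, 185 and 96 cells) edgeR called 0 (254 at unadjusted p under 0.05), with Nr4a3 at -1.84. There the proliferation list was called (adjusted p = 1.11e-05, 0.356 estimated) and the exhaustion list was not (0.0683). In the class the count was 5 and 12 without MiTE144 11 and 15, and 1, 61, 10 and 6 without aRSV 1, 2, 3 and 5. Single mice decided the call of Gadd45b (-1.83 without aRSV 1) and Dusp4 (-1.85, -1.75 and -2.03 without MiTE144 11, 12 and 14, -1.66 without aRSV 1).

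In monocytes and macrophages under MiTE144 the alarmin gene S100a8 rose, as did S100a9 at a far lower level, and 7 type I interferon genes fell. Against aRSV 64 genes rose and 124 fell of 11207. The alarmin S100a8 went to 137 ± 113 against 11.0 ± 9.68 CPM (adjusted p = 3.64e-04). Its partner S100a9 (+3.28 ± 0.69) rose too but stayed low, at 6.365 against 0.655 CPM. The ectoenzyme Cd38 (+2.72 ± 0.46), the guanylate-binding protein Gbp8 (+1.34 ± 0.28), the tetraspanin Cd9 (+0.92 ± 0.19) and nitric oxide synthase Nos2 (+2.34 ± 0.51) rose. The activation marker Cd83 (-1.91 ± 0.29), the interferon-induced Ifit3b (-1.79 ± 0.36), Usp18 (-1.17 ± 0.22) and Isg20 (-1.39 ± 0.27), the cyclic AMP-responsive Crem (-1.66 ± 0.25) and the nuclear receptor Nr4a2 (-1.59 ± 0.32) fell. In the type I interferon list 0 of 18 rose and 7 fell (list alone 0 and 14, adjusted p = 3.62e-13, 0.273 estimated). The neutrophil markers had a higher level (2 rose and 0 fell of 4, list alone 3 and 0, adjusted p = 3.48e-04, 0.0486 estimated). Of hypoxia and glycolysis genes 0 of 20 rose and 0 fell (list alone 10 and 0, adjusted p = 3.43e-07, 0.339 estimated). On leaving out 1 mouse the call ended for S100a9 (+2.88 without MiTE144 12) and Nos2 (+2.149 without aRSV 4).

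In the same cells the TREM2-associated list had members on both sides (1 rose and 1 fell of 25, list alone 7 and 2, adjusted p = 0.0832), and the mouse gene Trem2 itself was not called (+0.51 ± 0.43, adjusted p = 0.665). In the inflammatory cytokine list 0 of 17 rose and 1 fell (list alone 1 and 5, adjusted p = 3.47e-04, 0.312 estimated). Called were also the higher MHC class I and the lower dissociation stress and monocyte (adjusted p = 1.31e-04 to 0.0124, 0.339 to 0.562 estimated). Not called were interferon-gamma (1 rose and 2 fell of 30, list alone 5 and 2), MHC class II (0 of 7), proliferation (0 of 24) and macrophage markers (0 of 10, list alone 0 and 1), adjusted p = 0.0832 to 0.621. No filter gave 481 genes and DESeq2 321 in place of 188. The count moved to 124 and 114 without MiTE144 13 and 14, and 105 and 74 without aRSV 2 and 4.

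Set against the TREM2 antibody alone, the same 5 MiTE144 mice differed in 2 classes of the CD45 gate. Sharing these mice makes this comparison and that against aRSV alike even by chance. Granulocytes took a larger part of the CD45 gate (7.74% ± 4.61 against 1.72% ± 1.15, log2 +2.11 ± 0.51, adjusted p = 0.00344, exact p = 0.0159). Dendritic cells took a smaller part (3.02% ± 0.949 against 7.55% ± 3.49, log2 -1.29 ± 0.37, adjusted p = 0.00873, exact p = 0.0159). EdgeR called no other class of this gate, and the adjusted exact test, limited as above, 0. In the enriched gate the proliferating NK cluster was larger (18.2% ± 3.79 against 1.96% ± 0.703, log2 +3.24 ± 0.38, adjusted p = 1.09e-08). So were the proliferating CD8 cluster (7.09% ± 1.94 against 1.85% ± 1.85, log2 +1.94 ± 0.56, adjusted p = 0.00458) and T cells in early activation (6.03% ± 1.19 against 2.70% ± 1.36, log2 +1.18 ± 0.47, adjusted p = 0.0387). Early NK cells were fewer (6.93% ± 3.17 against 23.5% ± 3.26, log2 -1.72 ± 0.38, adjusted p = 5.14e-04). So were intermediate NK cells (7.53% ± 1.99 against 18.8% ± 3.85, log2 -1.29 ± 0.34, adjusted p = 0.00215). The call of T cells in early activation was lost with 1 mouse left out (+0.86 and +1.12 without aTREM2 6 and 8, +1.05, +1.18 and +1.20 without MiTE144 11, 12 and 13).

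In NK cells division genes were higher, and interferon and IL-2 target genes lower. Against aTREM2 499 genes rose and 473 fell of 9126. Of the proliferation list 26 of 26 rose and 0 fell (adjusted p = 6.58e-61, 1.79e-05 estimated), with Hist1h1b (+4.07 ± 0.56), the mitotic cyclin Ccnb2 (+2.91 ± 0.30) and Mki67 (+2.02 ± 0.21). The proteases Gzmk (+4.01 ± 0.34) and Gzma (+1.20 ± 0.22), and the receptor Klrg1 (+3.16 ± 0.26) rose, and the list called was NK maturation (4 rose and 1 fell of 12, list alone 5 and 1, adjusted p = 0.0201), adjusted p = 0.206 with an estimated correlation. In the type I interferon list 0 of 18 rose and 18 fell (adjusted p = 4.74e-29, 0.00419 estimated), with falls of Ifit3 (-2.66 ± 0.35), Rsad2 (-2.36 ± 0.38) and Slfn5 (-2.39 ± 0.34). In the IL-2 and STAT5 list 1 of 20 rose and 12 fell (adjusted p = 5.78e-09, 0.00216 estimated), including Bcl2 (-0.93), Ccnd2 (-1.06) and Il2ra (-0.94). Lower as well were interferon-gamma genes, of which 0 of 24 rose and 12 fell (list alone 1 and 15, adjusted p = 5.78e-09, 0.0223 estimated). The same held for MHC class I, monocyte, dissociation stress and macrophage markers (adjusted p = 2.98e-05 to 0.0210, 0.0407 to 0.127 estimated). The lipid carrier Apoe (-2.16) was among them. The chemokines Cxcl10 (-2.98) and Xcl1 (-2.05) fell. Without the proliferating cluster 152 genes were called, 131 of them among the 972, and Gzma then stood at -0.04. Dropping 1 mouse ended the call of Il2ra (-0.86, -0.84 and -0.95 without MiTE144 11, 14 and 15, -0.80 and -0.75 without aTREM2 9 and 10).

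CD8 T cells under MiTE144 carried more of the protease Gzma (+2.86 ± 0.53, adjusted p = 0.00742) than under aTREM2, and less of the phosphatase Dusp4 (-1.91 ± 0.37, adjusted p = 0.0131) and the cyclin Ccnd2 (-1.35 ± 0.24, adjusted p = 0.00742). In all, 7 genes rose and 12 fell of 5267. In the proliferation list 0 of 26 rose and 0 fell (list alone 4 and 0, adjusted p = 3.15e-13, 0.138 estimated). Called and lower were type I interferon, exhaustion and activation and regulatory T cell (adjusted p = 1.21e-05 to 5.06e-05, 0.0838 to 0.138 estimated). The count was 47 without a filter and 33 by DESeq2, and 2 without the proliferating CD8 cluster. Fewer mice gave 6, 5 and 11 without MiTE144 11, 12 and 13, and 11, 4 and 0 without aTREM2 7, 8 and 9. Past the threshold only with every mouse in were Gzma (+2.58 without aTREM2 9), Dusp4 (-1.81 without MiTE144 11, -1.79 without aTREM2 9) and Ccnd2 (-1.14 without aTREM2 9).

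Monocytes and macrophages under MiTE144 carried more Arg1 and Nos2 than under aTREM2. Here 104 genes rose and 158 fell. Arg1, which breaks down arginine, went to 1294 ± 528 against 192 ± 112 CPM (adjusted p = 4.45e-04). The alarmins S100a8 (+5.19 ± 0.59) and S100a9 (+4.43 ± 0.78), the elastase Mmp12 (+2.47 ± 0.52), the ectoenzyme Cd38 (+2.97 ± 0.46), Nos2 (+2.40 ± 0.50), the cytokine Il1a (+2.03 ± 0.43), the hypoxia gene Ndrg1 (+1.31 ± 0.23) and the checkpoint ligand Cd274 (+1.02 ± 0.23) rose. In the type I interferon list 0 of 18 rose and 15 fell (list alone 0 and 16, adjusted p = 4.32e-32, 0.0297 estimated), with Ifit3b (-2.39 ± 0.36), Ifit1bl1 (-2.17 ± 0.34), Isg20 (-1.78 ± 0.27) and Ifit3 (-1.75 ± 0.27) down. In the hypoxia and glycolysis list 3 of 20 rose and 0 fell (list alone 13 and 0, adjusted p = 1.2e-12, 0.137 estimated). Called were also the higher interferon-gamma, MHC class I and neutrophil markers and the lower macrophage markers (adjusted p = 0.00110 to 0.0366, 0.0557 to 0.796 estimated). Not called was TREM2-associated macrophage (4 rose and 3 fell of 25, list alone 5 and 6), adjusted p = 0.818. The count was 511 without a filter, and 165 without MiTE144 14, and 171 without aTREM2 7.

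The TREM2 antibody alone raised 1 gene of NK cells and none of CD8 T cells or of monocytes and macrophages. In NK cells the division gene Mki67 rose to 74.7 ± 12.6 against 25.0 ± 11.8 CPM (+1.48 ± 0.27, adjusted p = 0.0361), with all 5 aTREM2 mice above all 5 aRSV mice. It was the only gene called by edgeR of 9126 (566 at unadjusted p under 0.05, 3 by DESeq2). The call was lost with RLE scaling, without the proliferating cluster, with only the 2 groups in the fit, and without any of aRSV 2, 3, 4 and 5 and aTREM2 6, 8, 9 and 10 (0 genes each). In NK cells camera called 3 lists, 0 estimated (adjusted p = 0.323 to 0.575), among them proliferation (list alone 2 and 0, median +0.25, adjusted p = 3.64e-06) and type I interferon (median +0.22, adjusted p = 0.0220). In CD8 T cells edgeR called 0 genes (355 at unadjusted p under 0.05, 0 by DESeq2). In these cells camera called 3 lists, 0 estimated (adjusted p = 0.615), among them proliferation (median +0.45, adjusted p = 3.28e-04) and cytotoxic effector (list alone 1 and 6, median -0.13, adjusted p = 0.0247). In monocytes and macrophages edgeR called 0 genes (516 at unadjusted p under 0.05, 1 by DESeq2), 2 and 1 without aRSV 1 and 4, and 1 without aTREM2 9 and 10. There camera called 4 lists, 0 estimated (adjusted p = 0.116 to 0.670), among them type I interferon (median +0.29, adjusted p = 1.4e-08) and inflammatory cytokines (list alone 0 and 5, median -0.50, adjusted p = 1.9e-08). No cell class of the CD45 gate (lowest adjusted p 0.821) and none of the enriched gate (0.672) was called by edgeR.

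Adding aPD1 to MiTE144 changed few genes. In NK cells 4 genes rose and 0 fell of 9126, among them the poly(A)-binding protein Pabpc1 (+0.86 ± 0.16, adjusted p = 0.0235) (963 at unadjusted p under 0.05, 64 by DESeq2). The count was 9, 0, 0, 12 and 0 without MiTE144 11, 12, 13, 14 and 15, and 101, 0, 0, 0 and 0 without MiTE144+aPD1 16, 17, 18, 19 and 20. In NK cells camera called 6 lists, 0 estimated (adjusted p = 0.0710 to 0.555), among them interferon-gamma (median -0.27, adjusted p = 0.0107) and macrophage markers (list alone 0 and 2, median -0.25, adjusted p = 0.0107). CD8 T cells had 0 genes called by edgeR (289 at unadjusted p under 0.05, 1 by DESeq2). For them camera called 3 lists, 0 estimated (adjusted p = 0.744), among them proliferation (median -0.15, adjusted p = 0.0453). Monocytes and macrophages had 0 (1041 at unadjusted p under 0.05, 20 by DESeq2, 7 without MiTE144 11). In these cells camera called 6 lists, 0 estimated (adjusted p = 0.317 to 0.83), among them type I interferon (median -0.31, adjusted p = 0.00345) and inflammatory cytokines (list alone 1 and 5, median -0.47, adjusted p = 0.00109). No cell class passed the threshold in either gate (enriched gate 1 without MiTE144+aPD1 16). Single mice carried the calls of Pabpc1 (+0.82, +0.85 and +0.84 without MiTE144 12, 13 and 15, +0.84, +0.77, +0.77 and +0.90 without MiTE144+aPD1 17, 18, 19 and 20).

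In the aPD1 background the TREM2 antibody gave no called gene in the 3 classes within its batch. In monocytes and macrophages edgeR called 0 of 10655 genes (1016 at unadjusted p under 0.05, 6 by DESeq2, 1 without aTREM2+aPD1 26). All 18 type I interferon genes had a positive fold change. Here camera called 5 lists, 0 estimated (adjusted p = 0.220 to 0.372), among them type I interferon (list alone 3 and 0, median +0.26, adjusted p = 7.27e-08), hypoxia and glycolysis (list alone 0 and 5, median -0.40, adjusted p = 3.39e-10) and inflammatory cytokines (list alone 0 and 2, median -0.40, adjusted p = 2.05e-07). B cell markers, measured with 3 members in this comparison alone, gave their list (0 called of 3, list alone 1 and 0, adjusted p = 0.0634). In NK cells edgeR called 0 of 6464 genes (568 at unadjusted p under 0.05, 0 by DESeq2, 457 without the expression filter) and no list, the lowest adjusted p being 0.352. In CD8 T cells it called 0 of 2663 (184 at unadjusted p under 0.05, 3 by DESeq2, 176 without the filter). In these cells camera called 2 lists, 0 estimated (adjusted p = 0.195 to 0.479), among them proliferation (list alone 1 and 0, median +0.50, adjusted p = 6.87e-07). No class of the CD45 gate or cluster of the enriched gate was called by edgeR or by the exact permutation test.

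In the aCTLA4 background the TREM2 antibody again gave no called gene in the 3 classes. Monocytes and macrophages had 0 by edgeR (489 at unadjusted p under 0.05, 0 by DESeq2), NK cells 0 (632 at unadjusted p under 0.05, 0 by DESeq2) and CD8 T cells 0 (493 at unadjusted p under 0.05, 0 by DESeq2, 1 without aCTLA4 27). For monocytes and macrophages camera called 4 lists, 0 estimated (adjusted p = 0.566 to 0.580), among them type I interferon (median +0.20, adjusted p = 4.13e-04) and hypoxia and glycolysis (median -0.28, adjusted p = 1.01e-05). For NK cells camera called 7 lists, 0 estimated (adjusted p = 0.186 to 0.394), among them type I interferon (list alone 2 and 0, median +0.31, adjusted p = 5.32e-04) and TREM2-associated macrophage (list alone 0 and 1, median -0.38, adjusted p = 5.61e-06). For CD8 T cells camera called 6 lists, 0 estimated (adjusted p = 0.496 to 0.529), among them type I interferon (median +0.45, adjusted p = 0.0117). No cell class was called in either gate by edgeR or the exact test.

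Adding MiTE144 to aCTLA4 went with the same called classes of the CD45 gate as MiTE144 alone, in a separate batch. In the CD45 gate CD8 T cells were higher (6.11% ± 3.70 against 2.27% ± 0.664, log2 +1.48 ± 0.38, adjusted p = 0.00439, exact p = 0.0635). Granulocytes were higher too (5.16% ± 2.66 against 1.28% ± 0.598, log2 +1.91 ± 0.45, adjusted p = 0.00439, exact p = 0.0159), and dendritic cells lower (2.47% ± 1.33 against 6.20% ± 2.12, log2 -1.21 ± 0.36, adjusted p = 0.00922, exact p = 0.0238). The adjusted exact test, limited as above, called 0 (edgeR 3). In the enriched gate (n = 4 and 5), the proliferating CD8 cluster was larger (15.6% ± 4.07 against 3.86% ± 1.099, log2 +2.01 ± 0.32, adjusted p = 5.57e-05). So were the proliferating NK cluster (7.04% ± 2.68 against 1.99% ± 0.562, log2 +1.81 ± 0.33, adjusted p = 1.94e-04) and mature NK cells (23.1% ± 3.86 against 14.5% ± 1.77, log2 +0.67 ± 0.25, adjusted p = 0.0322). Early NK cells (8.82% ± 4.39 against 21.2% ± 4.27, log2 -1.31 ± 0.46, adjusted p = 0.0322) and intermediate NK cells (10.2% ± 2.42 against 16.4% ± 2.78, log2 -0.70 ± 0.28, adjusted p = 0.0374) were fewer. Early-activation regulatory T cells were fewer (0.683% ± 0.567 against 1.76% ± 0.623, log2 -1.48 ± 0.55, adjusted p = 0.0322). TMM scaling left 2 of these 6 calls. Only the calls of the proliferating clusters held without each mouse (others adjusted p = 0.0517 to 0.111). The number of calls was 2, 3 and 2 without MiTE144+aCTLA4 21, 24 and 25, and 3, 3, 2 and 3 without aCTLA4 27, 28, 29 and 30.

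In NK cells of the combination the division list was higher and the IL-2, interferon and naive and memory lists lower. Against aCTLA4 55 genes rose and 63 fell of 8076. Klrg1 stood at 289.8 ± 88.7 against 43.1 ± 22.6 CPM (adjusted p = 1.23e-06). The protease Gzmk (+3.15 ± 0.43), the interferon-inducible membrane protein Ifitm1 (+1.85 ± 0.33), Ccnb2 (+1.84 ± 0.28), the survivin gene Birc5 (+1.81 ± 0.29), the ubiquitin-conjugating enzyme Ube2c (+2.17 ± 0.40) and Mki67 (+1.23 ± 0.21) rose with it. In the proliferation list 10 of 25 rose and 0 fell (list alone 16 and 0, adjusted p = 1.37e-25, 0.00486 estimated). In the IL-2 and STAT5 list 0 of 20 rose and 6 fell (list alone 0 and 9, adjusted p = 1.25e-17, 3.75e-04 estimated), with falls of Ccnd2 (-1.29 ± 0.15), Pim2 (-1.49 ± 0.24) and Bcl2 (-0.96 ± 0.15). Among type I interferon genes 0 of 18 rose and 5 fell (list alone 0 and 10, adjusted p = 1.25e-17, 0.00486 estimated), with Ifit3 (-1.75 ± 0.28) down. Nlrc5 (-1.15 ± 0.22), Xcl1 (-1.89 ± 0.24) and the regulator Id2 (-0.69 ± 0.14) fell. Apoe (-1.82 ± 0.35) fell too, perhaps as macrophage RNA (NK over macrophage level 0.0072 under aRSV). Lower lists were also interferon-gamma, naive and memory, monocyte, dissociation stress and inflammatory cytokines (adjusted p = 3.3e-09 to 6.84e-04, 0.00486 to 0.0298 estimated). Lower with the preset correlation alone were MHC class I, MHC class II and macrophage markers (adjusted p = 1.56e-04 to 0.00825, 0.0685 to 0.0959 estimated). With only the 2 groups in the fit the count was 206. It was 78, 57 and 54 without MiTE144+aCTLA4 21, 24 and 25, and 77, 76 and 71 without aCTLA4 27, 28 and 30.

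In CD8 T cells of the combination, of 5646 genes 5 rose and 9 fell (n = 4 and 5 mice, 556 and 301 cells). The histone Hist1h1b (+1.41 ± 0.25, adjusted p = 0.00513) and the metallothionein Mt1 (+2.04 ± 0.36, adjusted p = 0.00513) rose, and the chemokines Ccl3 (-3.72 ± 0.69, adjusted p = 0.00725) and Ccl1 (-2.19 ± 0.41, adjusted p = 0.00725) fell. In the proliferation list 3 of 26 rose and 0 fell (list alone 7 and 0, adjusted p = 3.27e-09, 0.124 estimated). In the inflammatory cytokine list 0 of 3 rose and 2 fell (adjusted p = 2.24e-06, 0.0391 estimated), and so was dissociation stress, lower (adjusted p = 9.07e-05, 0.0391 estimated). Lower with the preset correlation alone were type I interferon, cytotoxic effector, exhaustion and activation and T and NK markers (adjusted p = 4.23e-08 to 0.00431, 0.0864 to 0.155 estimated). The count was 47 without a filter, 43 by DESeq2, 24 with mice of at least 30 cells, 34 with only the 2 groups in the fit, 0 without the proliferating CD8 cluster (141 at unadjusted p under 0.05), where the proliferation list was not called (adjusted p = 0.663), and 89 over all T cells other than regulatory ones. It was 9, 8, 5 and 4 without MiTE144+aCTLA4 21, 23, 24 and 25, and 6, 8, 8 and 30 without aCTLA4 26, 27, 28 and 30. Taking 1 mouse out ended the calls of Mt1 (+1.44 without MiTE144+aCTLA4 24), Ccl3 (-3.46 without MiTE144+aCTLA4 24) and Ccl1 (-1.87 without MiTE144+aCTLA4 25).

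Monocytes and macrophages of the combination had a higher hypoxia and glycolysis list and a lower type I interferon list. In all, 240 genes rose and 179 fell of 12174. In the hypoxia and glycolysis list 13 of 20 rose and 0 fell (list alone 18 and 0, adjusted p = 1.8e-24, 0.0375 estimated), with the lipid-droplet gene Hilpda (+2.02 ± 0.36), the oxidase Ero1l (+1.34 ± 0.22) and the angiogenic factor Vegfa (+1.31 ± 0.25). Arg1 stood at 2206 ± 1040 against 352 ± 97.4 CPM (adjusted p = 1.45e-04) and Nos2 at 262 ± 158 against 36.3 ± 10.9 CPM (adjusted p = 2.74e-05). The elastase Mmp12 (+2.83 ± 0.52), the activin subunit Inhba (+2.34 ± 0.41), the ectoenzyme Cd38 (+2.17 ± 0.45), the cytokine Il1a (+1.93 ± 0.37), the prostaglandin enzyme Ptgs2 (+0.90 ± 0.17), the metalloprotease Adam8 (+1.15 ± 0.21) and the checkpoint ligand Cd274 (+0.98 ± 0.21) rose. All 5 combination mice lay above all 5 aCTLA4 mice for Arg1 and Nos2. Of the type I interferon genes 0 of 18 rose and 16 fell (list alone 0 and 18, adjusted p = 4.34e-31, 0.0375 estimated), with Ifit3b (-2.32 ± 0.29), Ifit1bl1 (-1.84 ± 0.28), Isg20 (-1.81 ± 0.25), Ifit3 (-1.71 ± 0.26) and the interferon regulatory factor Irf7 (-0.90 ± 0.16). The fractalkine receptor Cx3cr1 (-1.12 ± 0.21), the membrane protein Ms4a7 (-1.099 ± 0.19) and the replication licensing gene Mcm5 (-1.39 ± 0.29) fell.

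Among the other lists of these cells, called were the higher exhaustion and activation and MHC class I and the lower proliferation (adjusted p = 5.79e-10 to 0.00580, 0.0750 to 0.346 estimated). Not called were TREM2-associated macrophage (6 rose and 1 fell of 25, list alone 7 and 2), inflammatory cytokines (3 rose and 1 fell of 17, list alone 6 and 3) and monocyte (0 rose and 2 fell of 12, list alone 2 and 2), adjusted p = 0.205 to 0.299. The mouse gene Trem2 (+0.05 ± 0.26, adjusted p = 0.967) was not called. The count of 419 became 640 without a filter, and 258 and 275 without MiTE144+aCTLA4 23 and 24.

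**Figure D4:**
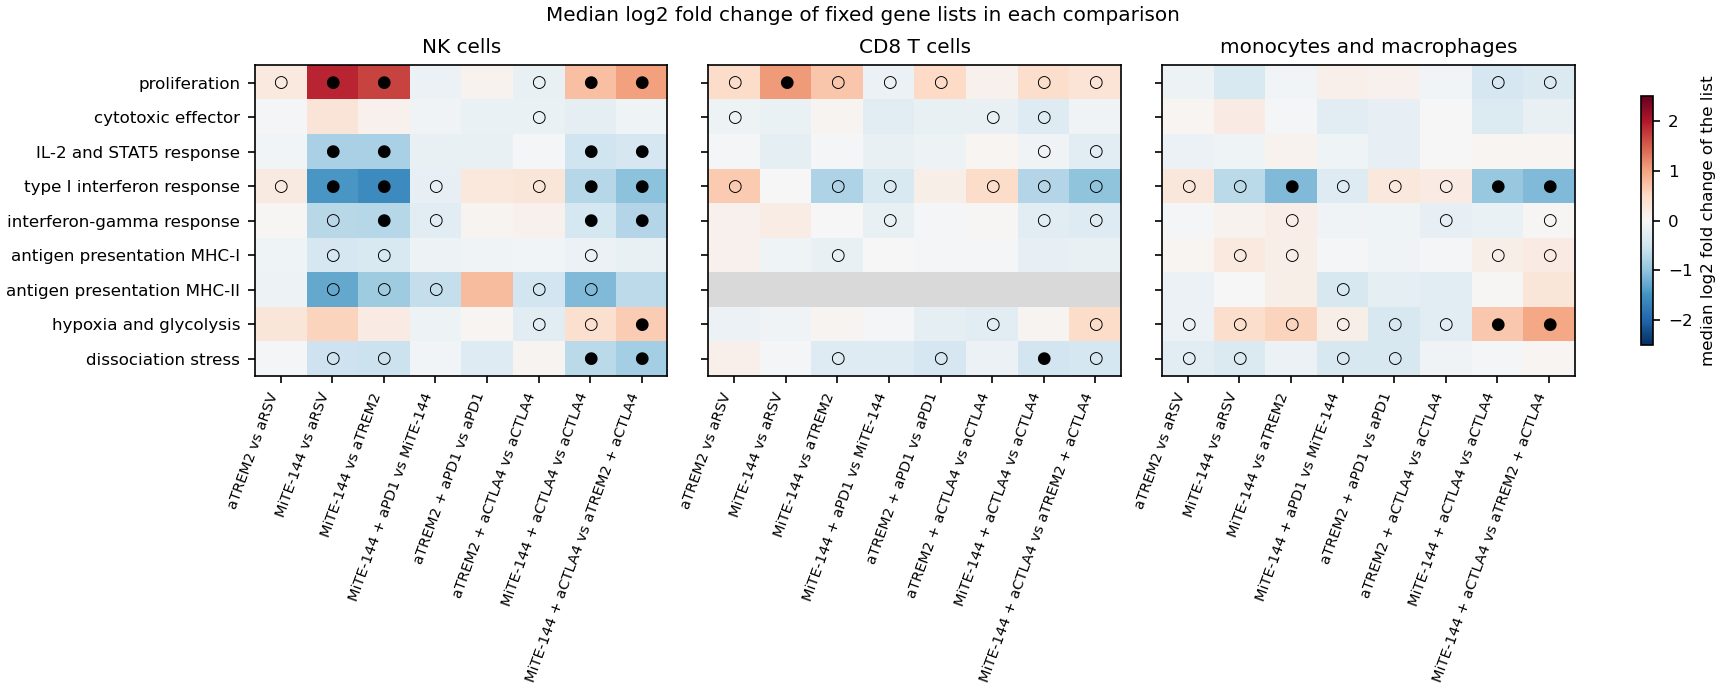
Median log2 fold change of the tested members of 9 gene lists in the 8 comparisons, for NK cells, CD8 T cells and monocytes and macrophages. A filled circle marks a camera adjusted p under 0.05 that also holds with an estimated correlation, an open circle one that holds with the preset correlation alone, and grey a list with fewer than 3 tested members. The type I interferon list in monocytes and macrophages is lower in all 4 comparisons of MiTE144 groups with groups lacking it.

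Against aTREM2+aCTLA4 the combination differed in 4 classes. In the CD45 gate CD8 T cells (6.11% ± 3.70 against 2.70% ± 0.918, log2 +1.30 ± 0.38, adjusted p = 0.0134, exact p = 0.103) and granulocytes (5.16% ± 2.66 against 1.82% ± 1.07, log2 +1.36 ± 0.45, adjusted p = 0.0181, exact p = 0.0476) were higher. Dendritic cells were lower (2.47% ± 1.33 against 7.31% ± 2.41, log2 -1.46 ± 0.36, adjusted p = 0.00649, exact p = 0.00794). Regulatory T cells were lower as well (0.903% ± 0.697 against 3.42% ± 3.81, log2 -1.64 ± 0.64, adjusted p = 0.0377, exact p = 0.0952), but aTREM2+aCTLA4 33 stood at 10.07% and the other 4 mice of its group at 0.753% to 3.01%. That call was lost with 1 mouse left out (-1.51, -1.51, -1.58 and -1.53 without MiTE144+aCTLA4 22, 23, 24 and 25, -0.55 without aTREM2+aCTLA4 33), as was that of granulocytes (+1.15 and +1.17 without MiTE144+aCTLA4 22 and 23). The adjusted exact test, limited as above, called 0, and edgeR 2 instead of 4 without MiTE144+aCTLA4 22 or 23. In the enriched gate 8 of 11 clusters were called, led by the proliferating NK cluster (7.04% ± 2.68 against 0.993% ± 0.563, log2 +2.56 ± 0.38, adjusted p = 2.23e-05) and the proliferating CD8 cluster (15.6% ± 4.07 against 4.54% ± 1.89, log2 +1.64 ± 0.32, adjusted p = 3.35e-04). Regulatory effector T cells (2.84% ± 1.79 against 13.4% ± 9.98, log2 -2.05 ± 0.55, adjusted p = 0.00516) and early NK cells (8.82% ± 4.39 against 15.9% ± 10.9, log2 -1.05 ± 0.46, adjusted p = 0.0498) were smaller. By the exact permutation test 2 clusters were called, with TMM scaling 5, and without MiTE144+aCTLA4 mouse 21 again 5. The early NK call was lost with 1 mouse left out (-0.79, -0.97 and -1.14 without MiTE144+aCTLA4 21, 24 and 25, -0.90, -0.95 and -0.89 without aTREM2+aCTLA4 31, 32 and 34).

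In NK cells division, hypoxia and glycolysis genes were higher as lists and interferon genes lower. In all, 116 genes rose and 159 fell of 8076. The metallothionein Mt1 (+2.99 ± 0.34), the granzymes Gzmf (+2.94 ± 0.52) and Gzmk (+3.92 ± 0.49) and the receptor Klrg1 (+2.90 ± 0.32) rose. So did Birc5 (+2.31 ± 0.31), Mki67 (+1.43 ± 0.22), the lipid-droplet gene Hilpda (+1.501 ± 0.24), the glycolytic Eno1 (+0.94 ± 0.20) and the checkpoint receptor Ctla4 (+1.93 ± 0.41). The interferon genes Ifit3 (-2.501 ± 0.28), Ifit1 (-2.10 ± 0.32) and Slfn5 (-2.34 ± 0.30) fell. Lower too were the aryl hydrocarbon receptor Ahr (-1.98 ± 0.35), Ccnd2 (-1.23 ± 0.15), the growth regulator Myc (-1.43 ± 0.30) and the naive-type factors Klf2 (-1.29 ± 0.27) and Satb1 (-1.24 ± 0.20). In the proliferation list 14 of 25 rose and 0 fell (list alone 20 and 0, adjusted p = 6.42e-28, 0.00394 estimated). For type I interferon genes 0 of 18 rose and 10 fell (list alone 0 and 18, adjusted p = 9.56e-23, 0.00329 estimated). In the hypoxia and glycolysis list 4 of 18 rose and 1 fell (list alone 10 and 1, adjusted p = 1.62e-07, 0.0280 estimated). Lower lists were IL-2 and STAT5, interferon-gamma, naive and memory, monocyte and dissociation stress (adjusted p = 1.67e-09 to 0.00105, 0.00329 to 0.0301 estimated). The TREM2-associated macrophage list had more rises than falls (3 rose and 1 fell of 9, list alone 5 and 2, adjusted p = 5.51e-04, 0.0824 estimated). Without the proliferating cluster 175 genes were called. The count was 183, 143 and 165 without MiTE144+aCTLA4 21, 24 and 25.

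In CD8 T cells 4 genes rose and 16 fell of 5646. The chemokine Ccl4 (-2.004 ± 0.38, adjusted p = 0.0178) fell and the metallothionein Mt1 (+2.16 ± 0.38, adjusted p = 0.0149) rose. Among type I interferon genes 0 of 15 rose and 4 fell (list alone 0 and 13, adjusted p = 7.22e-19, 0.0865 estimated). Called with it were the higher proliferation and hypoxia and glycolysis and the lower inflammatory cytokines (adjusted p = 9.19e-07 to 1.45e-04, 0.124 to 0.167 estimated). The count was 59 without a filter, 35 with mice of at least 30 cells, 6 with only the 2 groups in the fit, 2 without the proliferating CD8 cluster and 87 over all T cells other than regulatory ones. It was 9, 3, 0 and 1 without MiTE144+aCTLA4 21, 23, 24 and 25, and 8, 6 and 35 without aTREM2+aCTLA4 33, 34 and 35. A call that needed a particular mouse was that of Ccl4 (-1.80 and -1.83 without MiTE144+aCTLA4 24 and 25) and Mt1 (+1.56 without MiTE144+aCTLA4 24).

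Monocytes and macrophages gave the largest macrophage count of the 8 comparisons here. In all, 372 genes rose and 350 fell of 12174. Nos2 stood at 262 ± 158 against 22.2 ± 9.08 CPM (adjusted p = 3.17e-06). The arginine transporter Slc7a2 (+2.78 ± 0.30), Arg1 (+2.501 ± 0.37), Inhba (+2.81 ± 0.44) and Hilpda (+2.40 ± 0.37) rose. So did the glycolytic Aldoa (+1.06 ± 0.15) and Pkm (+0.77 ± 0.12), the cytokine Mif (+1.01 ± 0.16), Cd274 (+1.39 ± 0.22), the lectin Lgals3 (+0.81 ± 0.13), the protease Ctsl (+1.13 ± 0.17) and the transcription factor Bhlhe40 (+1.35 ± 0.20). Ifit3b (-2.67 ± 0.29), Isg20 (-2.16 ± 0.25), Ifit3 (-1.93 ± 0.26) and the antiviral GTPase Mx1 (-1.58 ± 0.24) fell. So did the monocyte genes Ccr2 (-0.73 ± 0.13) and Ly6c2 (-0.57 ± 0.12), the macrophage receptor Adgre1 (-0.66 ± 0.15) and the receptor chain Il2ra (-1.85 ± 0.36). Of the type I interferon genes 0 of 18 rose and 18 fell (adjusted p = 8.31e-36, 0.0217 estimated). In the hypoxia and glycolysis list 18 of 20 rose and 0 fell (list alone 19 and 0, adjusted p = 5.93e-32, 0.0217 estimated). In the TREM2-associated list 7 of 25 rose and 2 fell (adjusted p = 0.0102, 0.430 estimated). The exhaustion and activation list was higher with either correlation (adjusted p = 1.55e-07, 0.0413 estimated). Called with the preset one alone were the higher interferon-gamma and MHC class I and the lower proliferation and monocyte (adjusted p = 5.57e-05 to 0.0144, 0.279 to 0.533 estimated).

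The effect of MiTE144 without aCTLA4 (against aRSV) and with it (against aCTLA4) was measured on separate mice in separate batches. In NK cells 91 genes were called in both, all in the same direction. Of these 44 rose, where 4.11 would be shared by chance, and 47 fell, where 5.02 would be. Over 7953 genes the fold changes had a Pearson correlation of 0.483 (Spearman 0.355). In monocytes and macrophages 66 genes were called in both, 65 in the same direction, 25 up (by chance 1.25) and 40 down (by chance 1.93), with a correlation of 0.393 over 11092 genes. CD8 T cells shared 0 called genes, with a correlation of 0.261 over 4963 genes. Klrg1, Gzmk and Mki67 in NK cells and Nos2 and Cd38 in monocytes and macrophages rose in both batches, and Ifit3 fell in both.

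Whether an effect depended on the checkpoint antibody was tested as an interaction, in which batch and antibody cannot be told apart. In NK cells the MiTE144 effect differed with aCTLA4 for 8 of 9544 genes. Mki67 rose less with aCTLA4 (+1.21 ± 0.30) than without (+3.51 ± 0.35), a difference of -2.30 ± 0.46 (adjusted p = 0.0251). Ikzf2 (+1.76 ± 0.35), Fosl2 (+2.13 ± 0.43), Skil (+1.75 ± 0.36), Neurl3 (+1.498 ± 0.29) and Dgat1 (+1.89 ± 0.41) fell without aCTLA4 and were not called with it. Ccnd3 (-1.29 ± 0.28) and Magohb (-1.41 ± 0.31) differed the other way. With only the 4 groups in the fit 83 genes were called. Without 1 mouse the 8 became 0 to 21 (0 without MiTE144 11 or 12, MiTE144+aCTLA4 23, aCTLA4 28 or aRSV 5). In monocytes and macrophages Crem (+1.90 ± 0.35) and Ier3 (+1.51 ± 0.29) differed, and 17 with only the 4 groups. Here the count was 0 without MiTE144 11, 12 or 14, MiTE144+aCTLA4 22 or 23, aCTLA4 27 or 29, or aRSV 4 or 5. Its highest was 8.

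For the TREM2 antibody with and without aPD1, Slc16a3 (-3.94 ± 0.74), Casp6 (+5.57 ± 1.15) and Anapc1 (+3.21 ± 0.67) differed in NK cells, and 0 genes with only the 4 groups in the fit. Fewer mice gave 10, 0, 7, 11 and 0 without aPD1 21, 22, 23, 24 and 25, and 45, 35, 20, 42 and 51 without aTREM2+aPD1 26, 27, 28, 29 and 30, and 0, 1, 0, 0 and 0 without aRSV 1, 2, 3, 4 and 5, and 1, 1, 0 and 1 without aTREM2 6, 7, 8 and 9. In monocytes and macrophages Gzmc (-5.25 ± 0.74), Gss (+3.01 ± 0.59) and Dctn2 (-2.05 ± 0.41) differed, again 0 with only the 4 groups. There the count was 5, 1, 1, 10 and 8 without aPD1 21, 22, 23, 24 and 25, and 17, 21, 5 and 23 without aTREM2+aPD1 26, 27, 28 and 30, and 1 without aRSV 1, 2, 3, 4 and 5, and 1 without aTREM2 7, 8 and 9. In the 9-group fit all 6 genes were called with aPD1 (adjusted p = 1.41e-04 to 0.00242), in the fit of the batch none. The TREM2 antibody with and without aCTLA4 gave 0 genes by edgeR in NK cells (639 at an unadjusted p under 0.05), in CD8 T cells (343) and in monocytes and macrophages (370). CD8 T cells had 0 for the MiTE144 interaction as well (264) and 0 for the aPD1 one (486). Of 72 class-share interactions none passed 0.05, the lowest being the proliferating NK cluster (-1.60 ± 0.56, adjusted p = 0.0517) and regulatory T cells in early activation (-2.11 ± 0.78, adjusted p = 0.0517) for MiTE144 with aCTLA4.

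Levels of the targeted receptors are given side by side, untested across batches (mean ± SD, CPM). Mouse Trem2 in monocytes and macrophages ran from 5.92 ± 1.74 under aRSV to 24.9 ± 22.0 under aPD1, and was never called. Whether reads of the human TREM2 transgene enter these counts is not given in the sources used here. Pdcd1 in CD8 T cells, coding for PD-1, ran from 460.4 ± 71.5 under MiTE144 to 850.2 ± 494 under aTREM2+aCTLA4. Klrg1 in NK cells stood at 338 ± 60.7 under MiTE144, 335 ± 116 under MiTE144+aPD1 and 266 ± 75.7 under MiTE144+aCTLA4, against at most 55.5 ± 29.3 in the 6 other groups. Arg1 in monocytes and macrophages stood at 1317 ± 541, 2384 ± 918 and 2104 ± 995 in the same 3 groups, against at most 539 ± 285 in the others. Arg1 was not called for MiTE144 against aRSV (+1.45 ± 0.41, adjusted p = 0.0611), where aRSV 5 stood above 3 MiTE144 mice.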

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

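The interaction counts without the 2 mice of under 300 cells were chosen after the result was seen. Of 72 groups of 4 or 5 mice tested for a mouse far from the others, 3 had one, and chance gives about 1 in 20 groups. Regulatory T cells were 2.081% of the CD45 gate in MiTE144+aCTLA4 mouse 21, against 0.377% to 0.861% in the other 4 mice. They were 10.07% in aTREM2+aCTLA4 mouse 33, against 0.753% to 3.01%. The median UMI number per cell was 2204 in aTREM2+aCTLA4 mouse 32, against 3303 to 3430.

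A difference between groups was seen in 4 interaction tests. The MiTE144 effect differed with aCTLA4 for 8 genes in NK cells, where 2 of 100 relabellings of the mice within the 2 arms, the real one included, gave as many (highest other 41), and for 2 genes in monocytes and macrophages, where 3 did (highest other 64). The TREM2 antibody's effect differed with aPD1 for 3 genes in NK cells, where 47 did (highest other 72). It did for 3 in monocytes and macrophages, where 10 did (highest other 23). None of the 4 excludes chance. Relabelling also breaks the treatment effect within each arm, so it does not show which counts arise without an interaction. The other 5 tests had 0 genes, where all 100 relabellings give as many whatever the data and say nothing, with highest others of 1 in NK cells, 6, 7 and 2 in CD8 T cells and 1 in monocytes and macrophages. Relabellings that call several times the real count point to a structure of the samples, which was not tested. Without the 2 small mice the counts were 1 for the TREM2 antibody in NK cells and 0 for MiTE144 in monocytes and macrophages. Outside the authors' annotation, 26303 wells held 17.3% of all UMIs, which were not analysed here.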

How the results depend on the processing

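The fits without the 2 mice of under 300 cells, without the rRNA-like genes, without the proliferating NK or CD8 cluster and over all T cells other than regulatory ones were chosen after seeing the data, as were all alternatives for macrophage states and named genes, single-mouse values of called classes, and RLE and single-mouse fits of interactions. The others were chosen before. No paired analysis was possible because the replicate numbers count different mice and no 2 groups of a comparison share a number. Where a count moved by more than 1.5 times it is given with the reported count in parentheses, and the cause was not tested unless stated.

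RLE scaling ended 1 of 33 counts, in NK cells 0 (1) aTREM2 vs aRSV. Without an expression filter 6 of 24 gene counts stayed within 1.5 times, and the others were in NK cells 10 (1) aTREM2 vs aRSV, 38 (4) MiTE144+aPD1 vs MiTE144, 457 (0) aTREM2+aPD1 vs aPD1, 10 (0) aTREM2+aCTLA4 vs aCTLA4, and in CD8 T cells 15 (0) aTREM2 vs aRSV, 68 (3) MiTE144 vs aRSV, 47 (19) MiTE144 vs aTREM2, 176 (0) aTREM2+aPD1 vs aPD1, 13 (0) aTREM2+aCTLA4 vs aCTLA4, 47 (14) MiTE144+aCTLA4 vs aCTLA4, 59 (20) MiTE144+aCTLA4 vs aTREM2+aCTLA4, and in monocytes and macrophages 49 (0) aTREM2 vs aRSV, 481 (188) MiTE144 vs aRSV, 511 (262) MiTE144 vs aTREM2, 75 (0) MiTE144+aPD1 vs MiTE144, 2 (0) aTREM2+aPD1 vs aPD1, 30 (0) aTREM2+aCTLA4 vs aCTLA4, 640 (419) MiTE144+aCTLA4 vs aCTLA4. DESeq2 kept 13 of 24 within that range, and gave in NK cells 3 (1) aTREM2 vs aRSV, 64 (4) MiTE144+aPD1 vs MiTE144, and in CD8 T cells 34 (3) MiTE144 vs aRSV, 33 (19) MiTE144 vs aTREM2, 1 (0) MiTE144+aPD1 vs MiTE144, 3 (0) aTREM2+aPD1 vs aPD1, 43 (14) MiTE144+aCTLA4 vs aCTLA4, and in monocytes and macrophages 1 (0) aTREM2 vs aRSV, 321 (188) MiTE144 vs aRSV, 20 (0) MiTE144+aPD1 vs MiTE144, 6 (0) aTREM2+aPD1 vs aPD1. Of 21 counts with at least 30 cells per mouse 2 moved, in CD8 T cells 24 (14) MiTE144+aCTLA4 vs aCTLA4, 35 (20) MiTE144+aCTLA4 vs aTREM2+aCTLA4; no value could be had for the 3 CD8 comparisons among aRSV, aTREM2 and MiTE144. With only the groups compared in the fit 18 of 24 held, and others were in NK cells 0 (1) aTREM2 vs aRSV, 206 (118) MiTE144+aCTLA4 vs aCTLA4, and in CD8 T cells 8 (3) MiTE144 vs aRSV, 34 (14) MiTE144+aCTLA4 vs aCTLA4, 6 (20) MiTE144+aCTLA4 vs aTREM2+aCTLA4, and in monocytes and macrophages 2 (0) MiTE144+aPD1 vs MiTE144. Without rRNA-like genes 1 of 24 moved, in CD8 T cells 13 (3) MiTE144 vs aRSV. Over all T cells, which are more cells than the CD8 T cells, 3 of 8 moved, 185 (3) MiTE144 vs aRSV, 89 (14) MiTE144+aCTLA4 vs aCTLA4, 87 (20) MiTE144+aCTLA4 vs aTREM2+aCTLA4. Without the proliferating NK cluster 5 of 8 moved, in NK cells 0 (1) aTREM2 vs aRSV, 354 (1379) MiTE144 vs aRSV, 152 (972) MiTE144 vs aTREM2, 0 (4) MiTE144+aPD1 vs MiTE144, 175 (275) MiTE144+aCTLA4 vs aTREM2+aCTLA4. Without the proliferating CD8 cluster 4 of 8 moved, 0 (3) MiTE144 vs aRSV, 2 (19) MiTE144 vs aTREM2, 0 (14) MiTE144+aCTLA4 vs aCTLA4, 2 (20) MiTE144+aCTLA4 vs aTREM2+aCTLA4, all with fewer cells, and 1 value turned direction (Mki67 CD8: MiTE144_aCTLA4 vs aCTLA4, -0.000615). Without the NK cluster 5 gene values turned direction, Cma1 to -0.49 (MiTE144 vs aRSV), -0.27 (MiTE144 vs aTREM2) and -1.496 (MiTE144+aCTLA4 vs aTREM2+aCTLA4), and Gzma to -0.038 (MiTE144 vs aTREM2) and -0.29 (MiTE144+aCTLA4 vs aCTLA4). Without the 2 small mice 52 of 57 results held, and the rest were in NK cells 0 (1) aTREM2 vs aRSV, 0 (4) MiTE144+aPD1 vs MiTE144, in the CD45 gate 2 (4) MiTE144+aCTLA4 vs aTREM2+aCTLA4, and 2 interactions, 1 (3) for aTREM2 with and without aPD1 in NK cells and 0 (2) for MiTE144 with and without aCTLA4 in monocytes and macrophages.

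The exact permutation test of shares kept 18 of 24 class counts and gave in the CD45 gate 0 (3) MiTE144 vs aRSV, 0 (2) MiTE144 vs aTREM2, 0 (3) MiTE144+aCTLA4 vs aCTLA4, 0 (4) MiTE144+aCTLA4 vs aTREM2+aCTLA4, and in the enriched gate 3 (5) MiTE144 vs aRSV, 2 (8) MiTE144+aCTLA4 vs aTREM2+aCTLA4. TMM over classes kept 21 and gave in the enriched gate 2 (5) MiTE144 vs aRSV, 2 (6) MiTE144+aCTLA4 vs aCTLA4, 5 (8) MiTE144+aCTLA4 vs aTREM2+aCTLA4. Leaving granulocytes out or pooling both gates' T and NK cells moved 0 of 8 counts each. With only the 4 groups involved, the interaction counts were 83 (8) and 17 (2) for MiTE144 with aCTLA4 in NK cells and in monocytes and macrophages, and 0 (3) in each for aTREM2 with aPD1. Against 147 list calls an estimated correlation gave 37, fry 59 (4 new). Over genes past the threshold in either batch the correlation of the MiTE144 effects was 0.734 (0.483) in NK cells, 0.726 (0.261) in CD8 T cells and 0.71 (0.393) in monocytes and macrophages, as that choice keeps genes of large change.

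With each mouse left out in turn the counts ran, in NK cells 0 to 1 (1) aTREM2 vs aRSV, 0 to 101 (4) MiTE144+aPD1 vs MiTE144, 54 to 124 (118) MiTE144+aCTLA4 vs aCTLA4, 143 to 355 (275) MiTE144+aCTLA4 vs aTREM2+aCTLA4, in CD8 T cells 1 to 61 (3) MiTE144 vs aRSV, 0 to 20 (19) MiTE144 vs aTREM2, 0 to 1 (0) aTREM2+aCTLA4 vs aCTLA4, 4 to 30 (14) MiTE144+aCTLA4 vs aCTLA4, 0 to 35 (20) MiTE144+aCTLA4 vs aTREM2+aCTLA4, and in monocytes and macrophages 0 to 2 (0) aTREM2 vs aRSV, 74 to 217 (188) MiTE144 vs aRSV, 165 to 316 (262) MiTE144 vs aTREM2, 0 to 7 (0) MiTE144+aPD1 vs MiTE144, 0 to 1 (0) aTREM2+aPD1 vs aPD1, 258 to 456 (419) MiTE144+aCTLA4 vs aCTLA4. Class counts ran, in the CD45 gate 2 to 5 (3) MiTE144 vs aRSV, 2 to 4 (4) MiTE144+aCTLA4 vs aTREM2+aCTLA4, in the enriched gate 0 to 1 (0) MiTE144+aPD1 vs MiTE144, 2 to 7 (6) MiTE144+aCTLA4 vs aCTLA4, 5 to 8 (8) MiTE144+aCTLA4 vs aTREM2+aCTLA4, and in macrophage states 0 to 1 (0) aTREM2 vs aRSV, 0 to 2 (1) aTREM2+aPD1 vs aPD1. Interaction counts ran 0 to 21 (8) in NK cells, 0 to 2 (0) in CD8 T cells and 0 to 8 (2) in monocytes and macrophages for MiTE144 with aCTLA4, and 0 to 51 (3), 0 to 7 (0) and 1 to 23 (3) for aTREM2 with aPD1. Of 4810 values of named genes without 1 mouse 4256 kept their call or its absence, 553 lost the call and 1 gained it. RLE kept 480 of 481 such values, DESeq2 456, the fit without filter 462 and the fit without the small mice 465.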

Other observations

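Chosen only after the result was seen were the test of interferon-induced genes without the proliferating NK cluster, the shares of macrophage states and the averaging over 20 thinning draws. Summed over dendritic cells, the gene of a lectin that marks monocyte-derived dendritic cells was lower under MiTE144. Against aRSV 8 genes fell and 0 rose, led by Cd209a (-5.25 ± 0.52, from 890 to 26.3 CPM, adjusted p = 3.88e-08), the chemokine Cxcl10 (-2.10 ± 0.38) and the nuclear body gene Pml (-2.10 ± 0.46). With aCTLA4, measured in 3 mice against 5, Cd209a fell as well (-5.498 ± 1.03). In wells of regulatory T cells Cd83 (-3.81), the heat shock gene Hspa1a (-3.23) and Areg (-2.24) were lower and Emp1 (+2.63) higher, among 15 called genes. Against aTREM2 myeloid genes fell there (Lyz2 -2.97, Ly6c2 -2.37), so the source is open. Lyz2 also fell under aTREM2+aCTLA4 against aCTLA4 (-3.10). In T cells annotated as neither CD8 nor regulatory (Cd8a at 390 CPM), 15 genes rose and 68 fell, the tubulin regulator Stmn1 (+3.30) up and Cxcl10 (-2.88), the phosphatase Dusp4 (-2.70) and the nuclear receptor Nr4a3 (-2.68) down. Added to aCTLA4, MiTE144 lowered the cytokine Il17a (-3.54) there. In granulocytes, with 5 mice against 3, the cytokine Il6 fell (-6.55 ± 0.88) and the collagenase Mmp8 rose (+4.89).

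Within monocytes and macrophages of the CD45 gate, the Arg1 state was larger and the interferon state smaller under MiTE144. The Arg1 state was 13.5% ± 9.53 against 3.39% ± 0.859 under aRSV (log2 +1.999 ± 0.45, adjusted p = 8.68e-04), and the interferon state 4.89% ± 1.66 against 16.3% ± 8.94 (log2 -1.73 ± 0.33, adjusted p = 3.8e-04). With aCTLA4 they were 17.4% ± 6.40 against 3.23% ± 1.61 (log2 +2.42 ± 0.42) and 3.51% ± 2.81 against 13.9% ± 5.49 (log2 -1.90). Under aTREM2+aPD1 the interferon state was larger than under aPD1, 18.1% ± 2.79 against 10.3% ± 2.63 (log2 +0.82 ± 0.22, adjusted p = 0.0129), a call that became 0 states without aPD1 21 and 2 without aPD1 23. The states were named by genes that themselves differ, so they are not independent of the gene values.

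Of the 1379 NK genes changed by MiTE144 against aRSV, 22.2% were still called in the same direction without the cells of the proliferating cluster, which held 46.7% of NK UMIs under MiTE144 and 5.79% under aRSV. Median absolute change went from 1.07 to 0.721 and the standard error from 0.263 to 0.286, while at the same depth with all cells 80.5% were called, so more cells in that cluster may account for part of the pattern. It does not account for all, as 98.6% of those measured there kept their sign at a median fold ratio of 0.724, and 10 of 21 proliferation genes still rose and 9 of 19 IL-2 and STAT5 genes fell among 124 that rose and 230 that fell. With every mouse thinned to 254100 UMIs, 51.9% ± 1.03 (SD of draws) of calls were kept. These do not rest on unequal depth, the others may. Thinning itself fixes the fold ratio (1.00). What makes the cluster larger was not tested.

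Interferon-induced genes were lower in NK cells under MiTE144. Without the proliferating cluster their median log2 fold change was -0.942, which argues against that cluster as the cause. Their level in NK cells over that in macrophages was 35.5 times that of the macrophage markers in aRSV mice (medians 0.252 over 18 genes and 0.00709 over 10), which argues against macrophage RNA in NK wells, although the highest marker ratio, 1.969, lay above the lowest of an interferon gene, 0.1045. A response to treatment may therefore be a candidate explanation, found and tested on the same data.

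S100a8 rose in monocytes and macrophages under MiTE144. A share of 0.61% granulocyte RNA would give the rise, but over 7 other neutrophil markers the median of observed over expected rise was 0.000959 (range -1.77 to 1.97). This argues against granulocyte RNA as the cause, and a change within the cells may be a candidate explanation.

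Each gene count was set against 100 splits of the same mice, the real one included. Chance is less likely where only the real split gave as many genes (real count, highest other). NK cells had MiTE144 vs aRSV (1379, 70), MiTE144 vs aTREM2 (972, 37), MiTE144+aCTLA4 vs aCTLA4 (118, 8), MiTE144+aCTLA4 vs aTREM2+aCTLA4 (275, 105). CD8 T cells had MiTE144 vs aTREM2 (19, 5), MiTE144+aCTLA4 vs aCTLA4 (14, 11). Monocytes and macrophages had MiTE144 vs aRSV (188, 10), MiTE144 vs aTREM2 (262, 50), MiTE144+aCTLA4 vs aCTLA4 (419, 119), MiTE144+aCTLA4 vs aTREM2+aCTLA4 (722, 157). Fewer than 5 splits gave as many, but another gave more, with 3 for MiTE144+aPD1 vs MiTE144 in NK cells (4, 26), 3 for MiTE144 vs aRSV in CD8 T cells (3, 6), 2 for MiTE144+aCTLA4 vs aTREM2+aCTLA4 in CD8 T cells (20, 21). Over 24 counts that does not exclude chance. Nor could it be excluded with 10 for aTREM2 vs aRSV in NK cells (1, 3). For 0 called genes all 100 splits give as many whatever the data, so the test says nothing there (highest other): in NK cells aTREM2+aPD1 vs aPD1 (0), aTREM2+aCTLA4 vs aCTLA4 (2), in CD8 T cells aTREM2 vs aRSV (4), MiTE144+aPD1 vs MiTE144 (1), aTREM2+aPD1 vs aPD1 (2), aTREM2+aCTLA4 vs aCTLA4 (13), in monocytes and macrophages aTREM2 vs aRSV (13), MiTE144+aPD1 vs MiTE144 (4), aTREM2+aPD1 vs aPD1 (1), aTREM2+aCTLA4 vs aCTLA4 (14). Splits that call several times the real count, as for MiTE144+aPD1 vs MiTE144 in NK cells, point to a structure of the samples, which was not tested.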
